A study of Mus musculus with 6 samples.

How the data were processed

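RNA was measured in hematopoietic stem and progenitor cells of C57BL/6 mice aged 6 to 8 weeks. Per the labels' protocols, the cells were sorted from bone marrow as lineage-negative, Sca1-positive, c-Kit-positive, CD48-negative cells, in a CD150-positive and a CD150-negative gate, while the source field of each sample names the CD150-positive gate. Which of these gates a library holds is therefore not settled here. RNA was purified with the RNeasy Micro kit, made into libraries with the NuGen Ovation RNA-Seq System V2, a kit for small RNA amounts, and sequenced on an Illumina HiSeq instrument. The 3 wild-type samples carried Mx1-Cre, a Cre recombinase driven by an interferon-inducible promoter, and the 3 knockout samples carried Mx1-Cre with both copies of Yy1 flanked by loxP sites. The labels number the samples of each genotype 1 to 3 and do not say whether each came from its own mouse. Per-gene p-values therefore measure the spread between these libraries, part of which may be technical. The labels also do not say which part of Yy1 was deleted.

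Per the submitters' processing notes, the authors used the mm10 genome with Subread, featureCounts, edgeR and limma, with no versions, order or settings given. The deposited table lists 15553 genes left by a filter that is not given in the sources used here. The unit of the 6 library columns is not in the header and was found from the values: the authors' values behaved as RPKM, read counts scaled by gene length and by a library size. Multiplied by the exonic gene length of GENCODE release M21 (GRCm38, the assembly that mm10 names), the values of a library were whole multiples of 1 step, within a tolerance of 0.02 reads in all 6 libraries, for 11108 of the 15465 genes with a length (71.8%). Between 73.4% and 75.3% of the values of a library were whole. Why the remaining genes were not whole was not tested, and their recovered reads are estimates. The recovered reads in listed genes were 1.146 to 1.173 times the library size in wild type and 1.114 to 1.119 times it in knockout. Whether the authors scaled the library size, or the estimated reads are too high, was not tested. The other columns hold the authors' own comparison per the file headers, as a log2 fold change of knockout over wild type, a p-value and an adjusted p-value, and the authors' test behind them is not named. Coordinates are those of M21, matched by gene identifier. Every per-sample column was used.

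Reads recovered in the listed genes numbered 15102983 to 21757039 per library. Relative counting error at this depth grows as the reads of a gene become few, so reads are given for the thinly covered genes. The library kit amplifies RNA before sequencing, so reads are not independent molecules. Without a known strand setting in the counting, reads of overlapping genes cannot be told apart, and copies of near-identical sequence, such as histone and globin genes, pseudogenes and mitochondrial insertions, can share reads.

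The per-gene comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), for the 13179 genes with at least 1 RPKM in at least 3 libraries, with genotype as the term and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes of this fit are on the log2(RPKM + 0.5) scale, which understates the change of low genes. The wording of the test fixed before the data were examined, "trend and robust off", can be read as both options off or as a variance trend with robust fitting off, and the former is arguably the plainer reading. The variance trend was used. That choice was settled only after the results of both readings had been seen, because on simulated data the fit without the trend called 0 of 461 genes changed by 2 on the log2 scale. Both readings called 0 genes and 9 lists. With the trend, 1027 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0654, and without it 962 genes and 0.0589.

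On simulated reads of up to 12346 genes, in 5 runs with 200 changed genes each, modelled on this comparison, limma with the trend called 1.07% of genes changed by 1 on the log2 scale and 26.2% of genes changed by 2, with 21 false calls among 148. The limma-voom test on recovered reads, a test added after the data were examined, called 26.1% and 55.3%, with 22 false calls among 443. A simulated list of 30 raised genes was called in 5 of 5 runs by each fit, and 1 to 2 of 100 unchanged lists had a p under 0.05. The simulated genes were drawn independently of each other. These runs therefore do not show how often unchanged lists of correlated genes would be called. The voom fit took 13114 of the genes above that have a length, and a wider one took all 15465.

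Before the data were examined, 31 gene lists were fixed. The 26 with at least 5 tested genes, the sex-linked genes apart, were tested with camera, a competitive test of a list against all other genes. It used a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 26. At the preset correlation, its p-values rest on the spread among genes rather than on the spread between libraries. Other splits of the 6 libraries called up to 8 lists in this test, as given below. The list tests were repeated with an estimated correlation and with fry, a rotation test of whether the members of a list move on balance in one direction. The rule for named genes was also fixed then. It takes Yy1, its paralogs Yy2 and Zfp42, and Kit. It adds the 8 largest fold changes in each direction among genes past the adjusted threshold with a mean of at least 3 RPKM and no overlap between genotypes, leaving out unnamed gene models, then up to 4 members of a called list and up to 2 of any other list, by smallest p. In lists of other cell types the 2 members with the highest level may be given. As no gene passed, the same rule was applied at unadjusted p, where 658 genes were eligible. Genes named because the authors' deposited table calls them were chosen after their values were seen, as were the genes so marked elsewhere. Yy2 and Zfp42 were not analysed here, and some genes that the rule or the authors' deposited table would name are not reported here.

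Differences in library measures were tested with two-sided exact permutation tests, in which 3 libraries against 3 give no p below 0.1. The alternatives fixed before the data were examined were quantile normalization, median centring, no filter, a filter at 5 RPKM, array weights, pseudocounts of 0.1 and 1, a minimum log2 fold change of 1, a replicate block, the 2 other list tests, and leaving out each library. Added later were the voom fits and the fit without the variance trend. Alternatives that need raw counts were not run, since the recovered reads are whole for only part of the genes.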

Results

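Sorted hematopoietic stem and progenitor cells of mice labelled wild type and Yy1 knockout were profiled by RNA sequencing, with 3 libraries per genotype. YY1 is a zinc-finger transcription factor that also acts with Polycomb proteins. The study asked what its loss does to the resting state of stem cells. Reads in the listed genes numbered 15102983, 18460012 and 17346513 in wild type replicates 1 to 3 and 19473175, 19495401 and 21757039 in the knockout replicates (exact permutation p = 0.1, two-sided, the smallest this design allows). Genes listed at 0 numbered 1099, 747 and 1991 in wild type and 1071, 373 and 1075 in knockout. Spearman correlations across genes were 0.753 to 0.830 within wild type, 0.826 to 0.876 within knockout and 0.763 to 0.888 between genotypes. The first principal component, with 34.6% of the variance, set wild type replicate 3 apart from the other libraries.

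Yy1 (ENSMUSG00000021264, chromosome 12: 108792973 to 108820148) stood at 31.6, 42.3 and 52.1 RPKM in the wild-type libraries and at 36.2, 16.6 and 28.5 RPKM in those labelled knockout. The means were 42.0 ± 10.3 and 27.1 ± 9.85 RPKM (SD, n = 3 each; all later means are likewise ± SD over 3 libraries). The log2 fold change was -0.66 with a standard error of 0.32, and limma gave an adjusted p of 0.680, so the difference did not pass. The library labelled Yy1 knockout replicate 1 lay within the wild-type range and so did not bear out its label at this gene. The values cover the whole gene and can include reads from a part that was not deleted. Knockout below means the libraries so labelled, this one included.

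The 30 G2/M and mitosis genes rose as a list in camera, with a median log2 fold change of 1.42 and an adjusted p of 1.44e-26, which was 0.0932 with an estimated correlation. All 30 lay above 0, and none passed singly in limma. The members Kif11, Mki67 and Top2a, the last 2 named because the authors' deposited table called them, had no overlap between genotypes. Kif11, a spindle motor, went from 14.8 ± 0.412 RPKM in wild type to 40.6 ± 1.04 RPKM in knockout. Mki67, the gene of the proliferation marker Ki-67, went from 54.0 ± 22.4 to 153 ± 8.51 RPKM, and Top2a, which untangles DNA before division, from 30.2 ± 10.2 to 76.7 ± 2.35 RPKM. In the other direction, Txnip, which encodes the thioredoxin-interacting protein, went from 167 ± 40.9 to 56.0 ± 10.2 RPKM. Kit, the stem cell factor receptor, went from 126 ± 14.1 to 78.8 ± 3.27 RPKM.

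No single gene passed in limma on log2 RPKM, where 0 of 13179 genes had a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 1027 genes, 624 higher and 403 lower, where chance gives 659. The 3 values of one genotype lay clear of the 3 of the other in 1911 genes (14.5%), where chance gives 10%. A limma-voom fit of recovered reads called 8 of 13114 genes. Kif11, Mki67, Top2a, Cenpf and Aspm rose in that fit, and Txnip, Ndrg1 and the processed transcript RP23-110C17.2 fell. The number of voom calls was 0 without knockout replicate 2 and 0 without knockout replicate 3. It was 4 without wild type replicate 1, all among the 8, and 14 without wild type replicate 3, of which 7 were among the 8. A replicate block, which pairs the libraries by number, gave 72 voom calls, the 8 included. In limma, 1 gene passed without wild type replicate 1 (Gm23130) and 1 without wild type replicate 2 (Gm24455), both chosen after their values were seen.

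The authors' deposited table called 24 genes at an adjusted p under 0.05, 13 higher and 11 lower in knockout, with 1247 genes at an unadjusted p under 0.05. All 24 had the same sign in the limma fit and 21 had an unadjusted p under 0.05 there. The 8 voom calls were all among the 24. In the authors' deposited table, the higher genes included the kinetochore scaffold Casc5 at a log2 fold change of 1.71, the spindle gene Spag5 at 2.38, the cytokinesis gene Racgap1 at 2.05, the condensin subunit Ncapg at 1.90 and the DNA glycosylase gene Neil3 at 2.98. Arhgap19 stood at 2.74 there and the small GTPase gene Gem at 2.02, and the 5 higher genes of the voom fit were also among them. Among the lower genes of the authors' deposited table, Kit stood at -0.66, the stem cell transcription factor gene Hlf at -0.60, the small GTPase gene Rhob at -1.18 and Ndrg1 at -1.32. Also lower in the authors' deposited table were Txnip at -1.56, RP23-110C17.2 and the abundant RNAs Yam1, mt-Rnr1, mt-Rnr2 and Gm28437, the latter a pseudogene that can share reads with the mitochondrial genome. The gene listed as Yam1 took 633633 to 1138154 reads per library, and its values overlapped between genotypes. Whether these reads come from Yam1 RNA itself was not tested. Under quantile normalization, which gives the highest-ranked genes of each library the same set of values, the log2 fold change of mt-Rnr1 was 0.07 in place of -0.46, so that setting does not test its direction.

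**Figure D1:**
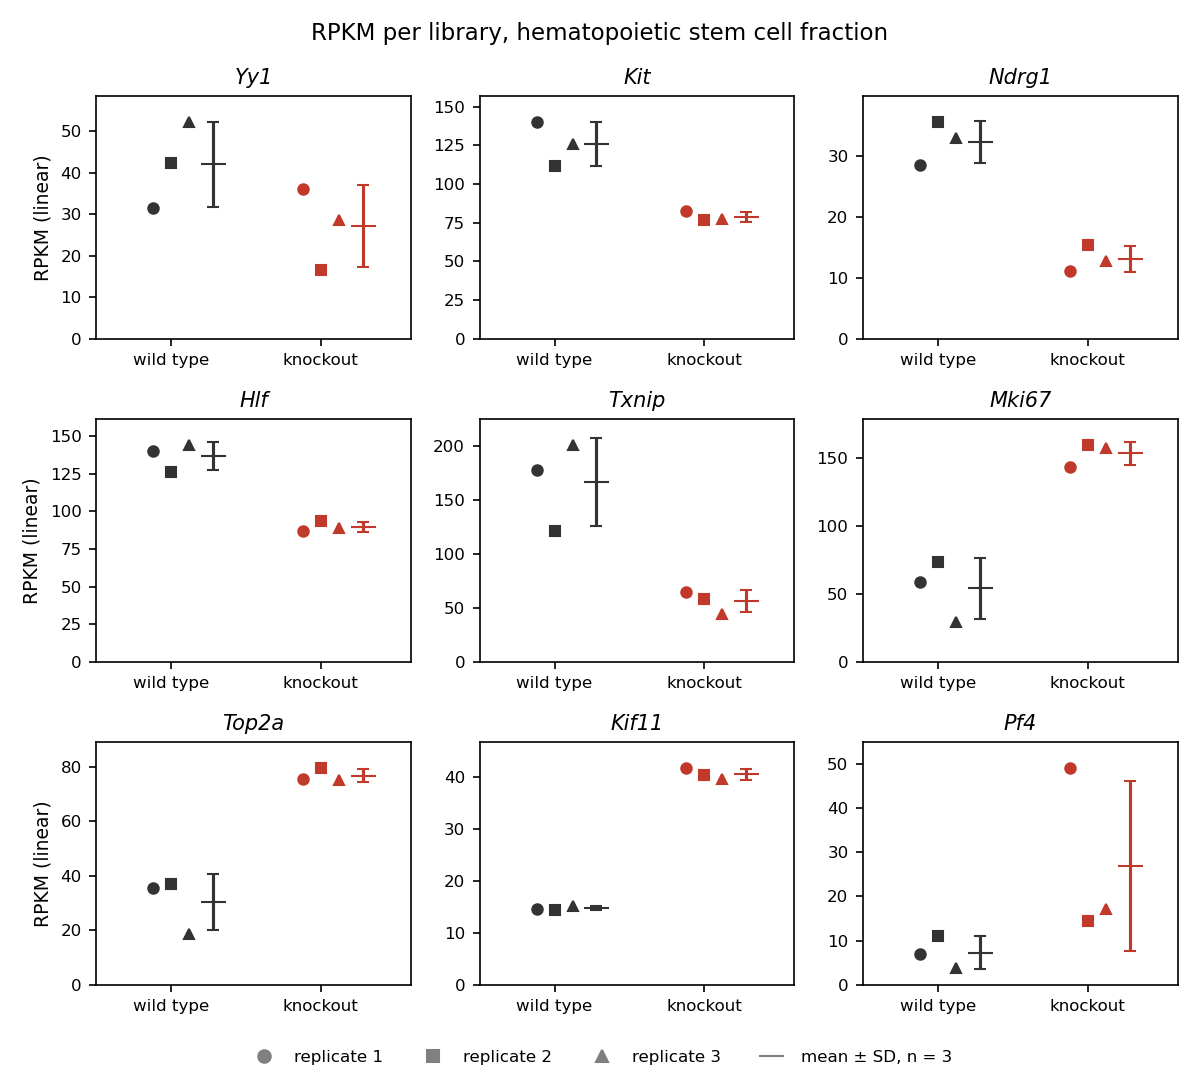
RPKM of 9 genes on a linear vertical axis in each of the 6 libraries, with wild type and knockout on the horizontal axis of each panel, 1 point per library, and the mean ± SD of 3 libraries as a line with whiskers. Kif11 in knockout (40.6 ± 1.04 RPKM) lay above wild type (14.8 ± 0.412 RPKM) without overlap, and Yy1 in knockout replicate 1 (36.2 RPKM) lay within the wild-type range (31.6 to 52.1 RPKM).

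Kit (ENSMUSG00000005672, chromosome 5: 75574916 to 75656722) stood at 140, 112 and 126 RPKM in wild type and at 82.6, 76.6 and 77.3 RPKM in knockout. Its log2 fold change was -0.67 with a standard error of 0.16. The adjusted p was 0.429 in limma and 0.0980 in limma-voom, and 0.0118 in the authors' deposited table. With a replicate block the limma adjusted p was 0.552, while limma-voom called Kit at an adjusted p under 0.05. The cells had been sorted on c-Kit protein, so the gate itself selects on the product of this gene. Without the library labelled Yy1 knockout replicate 1 the log2 fold change was -0.70.

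The largest fold changes at an unadjusted p under 0.05, none past the adjusted threshold, belonged mostly to thinly covered genes. Tpm4, a tropomyosin gene, went from 1.92 ± 0.651 to 22.8 ± 10.7 RPKM, a log2 fold change of 3.22. Atox1, a copper chaperone gene, had 1, 0 and 3 reads in the wild-type libraries and 93, 79 and 127 in the knockout libraries. Also higher were the respiratory assembly gene Cmc2, the RNA polymerase subunit gene Polr2k, the histone genes Hist1h2bm and Hist1h3a, the pseudogene Mrps36-ps1 and the small nucleolar RNA Snord55. Snord55 had 0 reads in each wild-type library against 16, 4 and 50. Zfp125, a zinc-finger gene on chromosome 12 (20877084 to 20921262), had the smallest adjusted p of all tested genes, 0.0654 in limma, with 47.8, 17.1 and 25.8 RPKM in wild type and 0.105, 0.105 and 0 RPKM in knockout. Mrps12, a mitochondrial ribosomal protein gene, went from 12.6 ± 4.99 to 1.04 ± 0.357 RPKM. Lower as well were Fgf3, Tmem203, Fkbp1b and the microRNA genes Mir7052, Mir1962 and Mir6374. Mir6374 had 49, 28 and 2 reads in wild type and 0 in each knockout library, and such small features can take reads of the genes they lie in.

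Further cell division lists rose as groups in camera, beside the G2/M and mitosis list, whose adjusted p was 0.0226 in fry. Of its 30 genes, 25 passed when adjusted over the list alone and 0 over all genes tested. Besides Kif11, the mitotic kinesin gene Kif20a had a log2 fold change of 1.72 with a standard error of 0.26. The kinetochore gene Ndc80 went from 8.34 ± 1.27 to 21.7 ± 3.60 RPKM and the spindle gene Nusap1 from 7.75 ± 1.66 to 26.4 ± 9.53 RPKM. Without the library labelled Yy1 knockout replicate 1 the list median was 1.41.

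The 30 replication and G1/S genes had a median log2 fold change of 0.58 (camera adjusted p = 1.10e-07), with 29 members above 0 and 0 past when adjusted over the list alone. With an estimated correlation the adjusted p was 0.295, and without wild type replicate 3 the median was 0.38. Mcm4, a helicase subunit gene, went from 41.0 ± 8.88 to 69.4 ± 1.98 RPKM, and the ribonucleotide reductase gene Rrm1 from 50.9 ± 12.7 to 94.8 ± 26.5 RPKM. Replication-dependent histone genes, which share near-identical copies, had a median of 0.67 over 32 tested members (camera adjusted p = 0.000193), with 26 above 0 and 3 past when adjusted over the list alone. Their adjusted p was 0.130 with an estimated correlation, and without wild type replicate 3 their median was 0.36. The linker histone gene Hist1h1b went from 22.1 ± 4.77 to 47.8 ± 8.05 RPKM.

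Cohesin and condensin genes had a median log2 fold change of 0.38 over 21 members (camera adjusted p = 0.000164), and 5 passed when adjusted over the list alone. Their adjusted p was 0.233 with an estimated correlation. The 4 members with the smallest p, Ncapg, Ncapg2, Smc2 and Smc4, all encode condensin subunits, which compact chromosomes in mitosis. Smc4 went from 41.4 ± 0.688 to 64.2 ± 1.23 RPKM. DNA repair genes had a median of 0.51 over 34 members (camera adjusted p = 7.05e-05), 28 of them above 0 and 0 past when adjusted over the list alone. With an estimated correlation this list had an adjusted p of 0.402, and without wild type replicate 3 its median was 0.30. The homologous recombination gene Brca2 went from 5.99 ± 1.37 to 11.5 ± 1.48 RPKM.

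Stem cell identity genes fell as a group. The median log2 fold change of the 27 members was -0.23 (camera adjusted p = 0.000164), 24 of them lay below 0, and 1 passed when adjusted over the list alone. Their adjusted p was 0.175 with an estimated correlation. Hlf went from 137 ± 9.40 to 89.7 ± 3.36 RPKM, the endoglin gene Eng from 31.9 ± 8.23 to 20.1 ± 2.08 RPKM and the RNA-binding protein gene Zfp36l2 from 341 ± 29.4 to 263 ± 12.9 RPKM. The quiescence list, which holds Txnip, did not pass (median 0.02, camera adjusted p = 0.332), and its mean of -0.04 and the direction of its test were opposite to its median. Its only member past when adjusted over the list alone was Txnip, and without wild type replicate 3 the list median was -0.35 at a camera adjusted p of 0.0370. The KIT signalling list did not pass either (median -0.03, camera adjusted p = 0.217), though its member Stat3 stood at 24.1 ± 1.90 RPKM in wild type and 14.3 ± 4.35 RPKM in knockout.

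**Figure D2:**
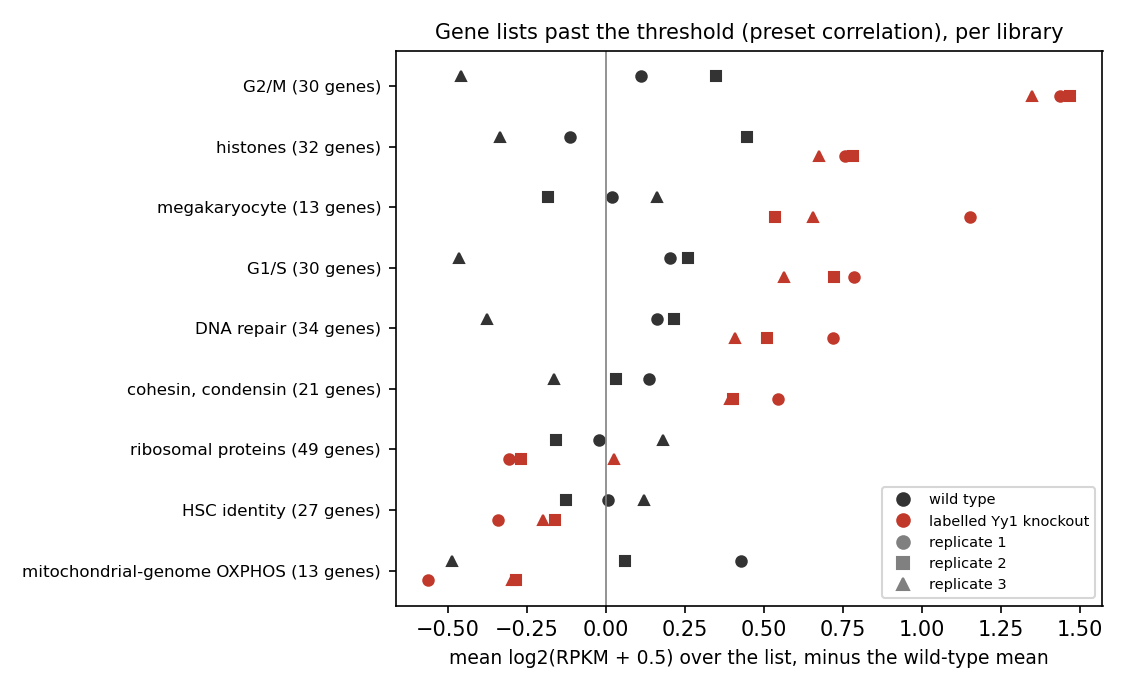
Mean log2(RPKM + 0.5) of the tested members of the 9 called gene lists in each library, less the mean of the 3 wild-type libraries, with 1 point per library. The G2/M list lay at 1.43, 1.47 and 1.35 in the knockout libraries and at 0.11, 0.35 and -0.46 in the wild-type libraries.

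Among markers of blood lineages, the megakaryocyte and platelet list rose, with a median log2 fold change of 0.59 over 13 tested members (camera adjusted p = 0.00126), 12 of them above 0 and 0 past when adjusted over the list alone. Its adjusted p was 0.231 with an estimated correlation. The platelet glycoprotein gene Gp9 went from 2.07 ± 0.600 to 7.45 ± 1.29 RPKM and Itga2b, the gene of CD41, from 14.1 ± 4.47 to 23.4 ± 5.59 RPKM. Pf4 stood at 49.0 RPKM in the library labelled Yy1 knockout replicate 1 and at 14.5 and 17.0 RPKM in the other knockout libraries, against 7.28 ± 3.69 RPKM in wild type. The list median was 0.40 without that library and 0.81 without knockout replicate 2.

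Erythroid markers had a median of 0.78 over 10 tested members and did not pass (camera adjusted p = 0.217). Granulocyte markers (median 0.82, camera adjusted p = 0.541), monocyte and macrophage markers (median -0.23, camera adjusted p = 0.332) and multipotent and lymphoid-primed progenitor markers (median -0.07, camera adjusted p = 0.332) did not pass. The median of the progenitor list turned to 0.14 without wild type replicate 1, 0.11 without knockout replicate 1, 0.09 with a pseudocount of 0.1, and 0.10 in voom and 0.15 there with all genes that have a length, and it was -0.18 without wild type replicate 3 and -0.31 under quantile normalization. Without wild type replicate 2 the granulocyte list passed, at a median of 1.80 and a camera adjusted p of 0.0273, while its median was -0.20 without wild type replicate 3 and -0.06 without knockout replicate 2. The erythroid list passed without knockout replicate 3, at 1.21 and a camera adjusted p of 0.0439, and its median was 0.47 without wild type replicate 1 and 0.47 without knockout replicate 2. The median of the monocyte and macrophage list turned to 0.37 with no filter and to 1.55 in voom with all genes that have a length, where 14 members were tested in place of 7. In the other direction, it was -0.43 without wild type replicate 1. Under the filter at 5 RPKM, with 5 members tested, the list passed at -0.36 and a camera adjusted p of 0.0489. Too few members for a test were left of the B cell list (1), the T and NK cell list (3), the mast cell, basophil and eosinophil list (1) and the endothelial and stromal list (3). Their most abundant members were Cd79b at 20.8 ± 7.70 RPKM in wild type and 14.9 ± 6.14 RPKM in knockout, Nkg7 at 9.55 ± 5.32 and 6.55 ± 2.39 RPKM, Cpa3 at 3.33 ± 3.57 and 1.72 ± 1.45 RPKM, and Pecam1 at 11.7 ± 3.19 and 10.3 ± 1.35 RPKM.

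Mitochondrially encoded messenger RNAs and ribosomal protein genes fell as groups in camera by small amounts, with overlap between the libraries of the genotypes. All 13 mitochondrial messenger RNAs lay below 0, with a median log2 fold change of -0.24 (camera adjusted p = 0.00175) and 0 past when adjusted over the list alone. Their adjusted p was 0.507 with an estimated correlation, which was 0.73, so the 13 members moved largely together. Against the wild-type mean, the list mean was 0.43, 0.06 and -0.49 log2 in wild type replicates 1 to 3. In knockout replicates 1 to 3 it was -0.56, -0.28 and -0.30. The cytochrome oxidase gene mt-Co2 went from 143 ± 46.5 to 78.4 ± 2.55 RPKM. Ribosomal protein genes had a median of -0.13 over 49 members (camera adjusted p = 0.00752), 33 of them below 0 and 0 past when adjusted over the list alone. For this list too the adjusted p was 0.507 with an estimated correlation. Its mean was -0.02, -0.16 and 0.18 log2 in wild type replicates 1 to 3 and -0.31, -0.27 and 0.03 in the knockout replicates. Rps14 went from 241 ± 67.3 to 137 ± 27.3 RPKM. Both lists lost the call under quantile normalization, the mitochondrial list also without wild type replicate 1 (median -0.14), and the ribosomal list without wild type replicate 3 (median -0.02), knockout replicate 1 (-0.08) or knockout replicate 2 (-0.06). The mitochondrial median was -0.43 without wild type replicate 3, and the ribosomal median -0.25 without wild type replicate 2 and -0.24 without knockout replicate 3. Beside these lists, the 3 most abundant RNAs, Yam1, mt-Rnr1 and mt-Rnr2, took 9.63% ± 1.03 of the reads in wild type and 7.10% ± 0.394 in knockout (exact permutation p = 0.1, the smallest possible), and mitochondrial genes took 6.26% ± 1.15 and 4.88% ± 0.241 (exact permutation p = 0.2).

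Nuclear-encoded respiratory chain genes (median 0.19, camera adjusted p = 0.217), mitochondrial ribosomal proteins (0.04, 0.332), ribosome biogenesis genes (0.13, 0.332) and glycolysis genes (-0.01, 0.339) did not pass. Without each library in turn, the medians of the last 3 lists ranged from 0.03 to 0.24, from 0.06 to 0.23 and from -0.11 to 0.00045, and none of them passed. In the glycolysis list the lactate dehydrogenase genes went opposite ways, Ldhb at a log2 fold change of -1.11 (standard error 0.29) and Ldha at 0.42 (standard error 0.17). Of the chromatin complexes tied to YY1, neither the Polycomb list (median -0.03, camera adjusted p = 0.375) nor the INO80 list (0.22, 0.805) passed, with medians of -0.08 to 0.02 and 0.15 to 0.26 without each library, and an INO80 median of -0.01 under the filter at 5 RPKM. The Polycomb subunit gene Suz12 stood at 28.8 ± 5.17 RPKM in wild type and 46.7 ± 2.45 RPKM in knockout, and Pcgf2 at 8.82 ± 2.54 and 2.63 ± 0.663 RPKM. Interferon-stimulated genes (median 0.27, camera adjusted p = 0.171), p53 targets (0.20, 0.522), apoptosis regulators (0.16, 0.332), imprinted genes (-0.19, 0.305) and immediate-early and heat shock genes (0.03, 0.885) did not pass. Without each library the p53 median ranged from 0.08 to 0.28, the apoptosis median from 0.12 to 0.24 and the imprinted median from -0.34 to -0.02, and none of these 3 passed. The imprinted list passed with no filter (median -0.27, camera adjusted p = 0.0278) and in voom with all genes that have a length (-0.30, 0.0331), where 18 members were tested in place of 10. The immediate-early and heat shock list had a mean of 0.06 and a test in the downward direction, and without wild type replicate 3 its median was -0.51 at a camera adjusted p of 0.00979. Without that replicate the interferon and nuclear respiratory chain lists passed as well, at medians of 0.18 and 0.19 and camera adjusted p values of 0.0395 and 0.0256. Without wild type replicate 1, wild type replicate 2 or knockout replicate 3, the interferon median was 0.15, 0.16 or 0.14 and the nuclear respiratory chain median 0.08, 0.10 or 0.11.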

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

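The voom fits and the fit without the variance trend were chosen after seeing the data. The count of 0 genes in limma stayed at 0 under quantile normalization, median centring, either pseudocount, no filter, a filter at 5 RPKM, a minimum log2 fold change of 1, the replicate block and the fit without the trend. Array weights gave 1 changed gene, 1 lower and 0 higher (Zfp125, adjusted p = 0.0331). Leaving out each library gave 0 to 1 changed and 0 to 1 higher genes, 0 of them lower. Voom on recovered reads gave 8 changed genes, 5 higher and 3 lower, and with all genes that have a length 9 changed, 5 higher and 4 lower, adding mt-Rnr2. Leaving out each library moved the voom count between 0 and 14. The cause of these moves was not tested. Kit kept its sign, with log2 fold changes of -0.75 to -0.59 and limma adjusted p values of 0.335 to 0.896 without each library, and adjusted p values of 0.0703 to 0.608 under the other limma alternatives and voom without the block, but it was among the 72 genes called in voom with the replicate block. Yy1 kept its sign at -0.90 to -0.35 without each library.

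Of the 16 genes named by size, 9 had an unadjusted p under 0.05 under the filter at 5 RPKM, where only 9 were tested, and 9 in voom on recovered reads, where 15 were tested and the cause was not tested. Leaving out each library gave 15 to 16. The 9 called lists became 0 with an estimated correlation and 1 (G2/M) in fry, 7 to 11 under the other alternatives and 8 to 12 without each library. With no filter the erythroid and imprinted lists were added, and with the filter at 5 RPKM the monocyte and macrophage list. Without wild type replicate 3, the quiescence list median turned to -0.35 and the immediate-early list median to -0.51, both past the threshold, and the cause was not tested. Over the fits without each library the quiescence median ranged from -0.35 to 0.25 and the immediate-early median from -0.51 to 0.46. Sign changes occurred in 0 of 171 values of called lists, in 21 of 323 values of the 17 other lists, these 2 included, and in 15 of 1247 values of the named genes, in 7 genes. Every scaling moved the median log2 fold change of all genes by less than 0.1.

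The sample titles number the replicates alike in both genotypes, but the column name of knockout replicate 3 carries a different number. The deviations of same-numbered libraries correlated at only 0.02, 0.06 and 0.05 across genes. Against the wild-type mean, the granulocyte list mean was 1.66 log2 in wild type replicate 2 and 1.93 in knockout replicate 2. In wild type replicate 3 and knockout replicate 3 it was -1.55 and 0.05. Whether the numbers pair the libraries is not settled, and the main fits do not pair them. The replicate block gave 0 genes in limma, 9 lists and 72 genes in voom, the 8 among them. Each wild-type library correlated best with its own number except wild type replicate 1, at 0.02 with knockout replicate 1 and 0.04 with knockout replicate 2. Normalizations and tests that need raw counts (RLE, upper quartile and count models) were not run. Genes with few reads, such as Snord55 and Mir6374, are limited by depth.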

Other observations

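The tests of the progenitor list, of the megakaryocyte list, of the cells that kept Yy1 and of the neighbours of Meg3 were chosen only after the values they measure had been seen. Interferon-stimulated genes did not pass as a list, with 6 of 37 members at an unadjusted p under 0.05, all higher in knockout, and 12 members below 0. Of the members with the smallest p, Ifit1 had a log2 fold change of 1.29 with a standard error of 0.31, and the transcription factor gene Irf7 was at 5.76 ± 3.03 RPKM in wild type and 15.1 ± 2.73 RPKM in knockout (SD, n = 3). The costimulatory receptor gene Cd27, a marker of early progenitors, was at 51.2 ± 10.1 and 24.5 ± 6.07 RPKM. None of these passed in limma (adjusted p = 0.429 for Ifit1, 0.557 for Irf7 and 0.429 for Cd27).

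Higher G2/M genes in knockout, at a list median of 1.42 on the log2 scale, were set against 4 explanations. Thinning all libraries to the smallest total of reads left the median at 1.42. RPKM is already scaled by library size, so thinning hardly moves genes with many reads and cannot decide on depth. Leaving out wild type replicate 3 left the median at 1.16, which argues against that library as the whole cause. A larger share of multipotent and lymphoid-primed progenitors stays open. Of the 11 tested members of that list, 5 lay above 0, and its median, -0.0728, ranged from -0.18 to 0.14 without each library. The list median replaced a first measure on Flt3 (-0.47) and Cd34 (-0.38) alone. Only Cd27, lower at a log2 fold change of -1.06, passed when adjusted over the list alone, and the other 10 members did not. A larger share of megakaryocyte-primed cells also remains a candidate explanation, since the megakaryocyte list median was at its lowest 0.40 over the fits with all libraries and without each. An effect of genotype on cycling also stays open and was not separated from a change in cell makeup.

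Yy1 RNA in the library labelled Yy1 knockout replicate 1, at 36.2 RPKM, lay within the wild-type range. On the 60 genes with the smallest p in a voom fit without it, its median position between the wild-type mean (0) and the mean of the other knockout libraries (1) was 0.821, with quartiles of 0.571 and 1.05, and medians of -0.199 to 0.175 for the wild-type libraries. The wild-type libraries helped to choose the genes and set the 0, so their medians must lie near 0. No wild-type library was scored while held out, and choosing genes in this way can raise a held-out position above 0. Within that limit, the position of 0.821 argues against a wild-type library under a wrong label. The G2/M shift of knockout replicate 1 exceeded the lower of the other knockout shifts by 0.0878 on the log2 scale. The rule for this comparison was written after the shifts of knockout replicates 1 to 3, 1.43, 1.47 and 1.35, had been seen. It therefore cannot decide on a larger share of cells that kept Yy1 and behave as wild type. On this 1 list, knockout replicate 1 lay with the other knockout libraries. The library also held Xist RNA beside RNA of Y-linked genes, as given below. Whether that bears on its Yy1 value was not tested. Reads from an undeleted part of the gene may be present, a possibility that the table cannot test because it holds 1 value per gene.

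Meg3, an imprinted long noncoding RNA on chromosome 12 (109541001 to 109571726), 721 kb beyond Yy1, had 498, 733 and 265 reads in wild type and 0, 21 and 14 in knockout, and was below the expression filter. The authors' deposited table gives it a log2 fold change of -6.72 at an adjusted p of 0.219. The neighbouring Rian had 149, 400 and 1018 reads against 92.9, 7.3 and 35.5, and Gm37899 had 49, 37 and 95 against 0, 0 and 0. The other 6 tested genes within 1 Mb of Yy1 or Meg3 had a median log2 fold change of 0.14 (SD 0.37, range -0.27 to 0.82). This measure replaced a first one, the share of them at an unadjusted p under 0.05 (0%, against 7.79% of all tested genes). None of the 6 lies between positions 109028452 and 110447120, the stretch that holds Meg3, Rian and Gm37899. They argue against a loss of RNA that takes in the tested genes around Yy1. A loss limited to the stretch around Meg3 is not tested by them. Random dropout in low-input libraries stays open, because 2 other genes, Zfp125 (lost) and Ptprm (gained), were at 200 or more reads in each library of 1 genotype and at 25 or fewer in each of the other.

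With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In limma the real split gave 0 genes, so 10 of the 10 splits had to give as many (highest other 3), and this count decides nothing. In voom 1 of the 10 did (real 8, highest other 2), and for called lists 1 of the 10 (real 9, highest other 8).

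Some genes varied between libraries of 1 genotype, and they were chosen after their values were seen. Camp was at 16.7 RPKM in wild type replicate 2 and 50.5 RPKM in knockout replicate 2, and S100a9 at 86.4 and 149 RPKM there, while the other 4 libraries had at most 2.16 RPKM of Camp and 36.3 RPKM of S100a9. The immediate-early gene Egr1 was at 198 and 183 RPKM in these libraries and at 41.8 to 109 RPKM in the others, and Nr4a1 at 89.5 and 120 RPKM against 13.0 to 35.7 RPKM. Xist was at 12.8 RPKM, about 4009 reads, in the library labelled Yy1 knockout replicate 1 and at 0.313 RPKM or less in the other 5, while the Y-linked genes Ddx3y and Eif2s3y were present in all 6, at 22.8 and 24.8 RPKM in that library.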
